A study of Homo sapiens with 11 samples.

How the data were processed

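Total RNA of 11 NT2D1 samples, 5 non-induced and 6 induced with doxycycline, was labelled as biotin cRNA and hybridised to Illumina bead arrays, one array per sample. The deposited non-normalized table holds an intensity per probe and array on a linear scale, without subtraction of background, for 48803 probes. Beside each signal the deposited table holds a detection p-value, in steps of 1 over 759, as from a rank among negative control probes. A matrix by the authors holds the same intensity after quantile normalization over the 11 arrays, on a linear scale: its sorted values differ from the mean of the sorted raw columns by at most 0.0549%, its columns share a median of 82.5, and each has a rank correlation of 1 with its own raw column. The authors' processing notes name limma without a version. All columns of per-sample values were used, and 0 pairs of arrays had identical values. Correlations of the normalized values between arrays lay between 0.939 and 0.988.

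The non-normalized intensities were processed with neqc of limma 3.58.1 in R 4.3.3 (statmod 1.5.0), which estimates background from the detection p where control probes are absent, adds an offset of 16, takes log2 and normalizes by quantiles. Probes were kept with a detection p under 0.01 on at least 5 arrays, which left 14338. Of all probes 28098 had 1 gene symbol, 13 had several and 20692 were unnamed here; of the kept probes 12341 had 1 symbol and 1997 were unnamed or had several. Gene lists used, for each of 9854 genes, the kept probe with the highest mean over all samples, and 2109 of these genes had more than 1 kept probe. Of the named genes 42 had more than 1 kept probe, and in 36 of these all probes had a difference in the same direction. The others were JADE1, DHX9, PDGFRA, TEAD4, RPS24 and TFAP2A.

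Induced samples were compared with non-induced samples with limma on all 11 samples, with no other term, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. A model of group, title prefix and their interaction gave the effect in each prefix and the difference between them, and a model of group and prefix gave the difference in level. Differences are given as log2, induced minus non-induced or prefix 5 minus prefix 1, with the standard error (SE) of limma, or for a list the SE between samples of its mean score. Single values per sample were compared with an exact two-sided permutation test over the 462 splits of 5 against 6 samples, whose smallest p is 0.00216. A fold against a group with every sample at or below background is given as a lower bound against the detection level; for a difference between effects the fitted value is given, and said to rest on such groups.

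There were 23 gene lists, without L1TD1. They were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists, with an estimated correlation and with fry. Past the threshold were 4 lists with the preset correlation, 0 with an estimated correlation, 1 in fry and 1 after adjustment in an exact permutation of the list scores, which was added after seeing the data. Lists within each prefix and the exact permutation within prefixes, over 200 arrangements with a smallest p of 0.005, were also added then. The lists, the comparisons, the filter, the other settings except those said to be added and the rule for named genes were fixed before the data were examined. Several lists share genes; 2 of the 29 measured ATF4 genes, 8 of the 27 matrix and adhesion genes, 7 of the 18 let-7 targets and 4 of the 32 pluripotency factors are also in another list.

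Genes were named by this rule: L1TD1, POU5F1, SOX2, NANOG, LIN28A and DNMT3B always; up to 10 with the largest rise and up to 10 with the largest fall among those past the threshold with the same direction in all 5 pairs of same-numbered samples, counting genes by their brightest probe, of which 5 passed; the 4 members of each list with the smallest p; and the 5 with the smallest adjusted p for the prefix comparisons. Other genes are said to be chosen after their values were seen; the examples from the effect in prefix 1 are members that the rule had named for their lists.

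The design text gives 6 clones with a non-induced and an induced sample each. The replicate numbers run from 1 to 6, same-numbered samples share a title prefix, and their title numbers differ by 9 in all 3 pairs of prefix 1 and by 11 in both pairs of prefix 5, so the number is taken as the clone, though no label states it, a reading settled after both fits had been seen. Deviations of same-numbered samples from the group means correlated between -0.19 and 0.40, over 0.1 in 1 of 5 pairs, and 1 of 5 non-induced samples correlated best with its own number. The comparison was fixed without the replicate number, with the number as a block as the alternative; exact permutation tests do not use the pairs. Alternatives were the replicate number as a fixed or a random block, with lists under the random block ranked by moderated statistics, the title prefix as a block, each prefix alone, no background correction, background by maximum likelihood with an offset of 50, scaling to a common median, the authors' matrix, no detection filter, detection on all 11 arrays, array weights, a variance trend with robust estimates, a fold change of at least 1.5, and leaving out each sample. A slide block was not run, since the files name no slides. Added after seeing the data were the replicate block for the effect in each prefix and the difference between them, leaving out non-induced sample 3 with dox-induced sample 5, which deviate together, and the p53 targets without genes of the ATF4 list.

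The comparisons were tested on simulated data built on the same probes and group sizes. A simulated 1.5-fold change was called in 34.3%, a 2-fold change in 85.1% and a 3-fold change in 95.4% of probes for induced against non-induced samples, with 3 false calls. For a 2-fold change the share was 47.8% for the effect in prefix 1, 19.4% in prefix 5, 5.97% for the difference between these effects and 73.1% for the level between prefixes. Of 100 simulated lists of 25 genes, the 1 shifted by 0.5 was called and 0 of the others were in camera, while 7 of the others had an exact permutation p under 0.05. Simulated probes varied independently of each other and held no clone effect, so these shares do not cover genes that vary together. Those for induced against non-induced samples also held no difference between prefixes. On the real arrays 11.4% of probes differed in level between prefixes at an unadjusted limma p under 0.05. The shares for that comparison may therefore be too high. In the real data the estimated correlation was 0.26 for the ATF4 list and 0.33 for the interferon list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The sample left out of the series by the submitters was not analysed here.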

Results

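Gene expression was measured on Illumina bead arrays in NT2D1 cells, a human embryonal carcinoma line that expresses many genes of embryonic stem cells. The cells stably carried a tetracycline repressor and a doxycycline-controlled short hairpin RNA (shRNA) against L1TD1, an RNA-binding protein of undifferentiated cells. There were 11 samples of total RNA from day 6, of which 5 were non-induced and 6 were induced with doxycycline. Sample titles begin with 1 or 5, called title prefix here, and the file headers use the same number in the name of an shRNA. Prefix 1 held 3 non-induced and 3 induced samples, and prefix 5 held 2 and 3. The submitters state that a sample which did not group with its condition was left out of the series, a selection that favours differences between the groups.

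Between 13301 and 15127 of the 48803 probes on each array were above background at a detection p under 0.01, which is 27.3% to 31.0%. The mean was 14184 ± 607 probes (SD, n = 5) in non-induced and 14130 ± 692 (SD, n = 6) in induced samples, a difference of -54.7 probes (exact two-sided permutation p = 0.950). Mean raw intensity was 427 ± 29.2 (SD, n = 5) in non-induced and 373 ± 26.8 (SD, n = 6) in induced samples (exact two-sided permutation p = 0.0152). Raw intensity therefore moved with the groups, and the comparisons below use values quantile normalized across arrays, except in the alternative with scaling to a common median. The number of arrays limits the precision of every value.

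L1TD1, the target of the shRNA, was lower in induced than in non-induced cells. Its probe ILMN_1769839 had a mean log2 level of 8.74 ± 0.17 (SD, n = 5) without and 7.84 ± 0.37 (SD, n = 6) with doxycycline. The difference of -0.91 ± 0.18 (SE) leaves 53.4% of the non-induced level, and all 6 induced samples lay below all 5 non-induced samples. The remaining level was 50.6% in prefix 1 (log2 difference -0.98 ± 0.23, SE) and 54.7% in prefix 5 (-0.87 ± 0.25, SE). The exact two-sided permutation p was 0.00433, against a smallest possible 0.00216, while the limma p adjusted over 14338 probes was 0.0753. Without dox-induced sample 5, the only left-out sample that changed this call, the adjusted limma p was 0.0351 at a difference of -1.004. With the authors' normalized values L1TD1 passed as well, at -0.75 (adjusted p = 0.0435, over a range of 0.0351 to 0.835 across the alternatives).

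**Figure D1:**
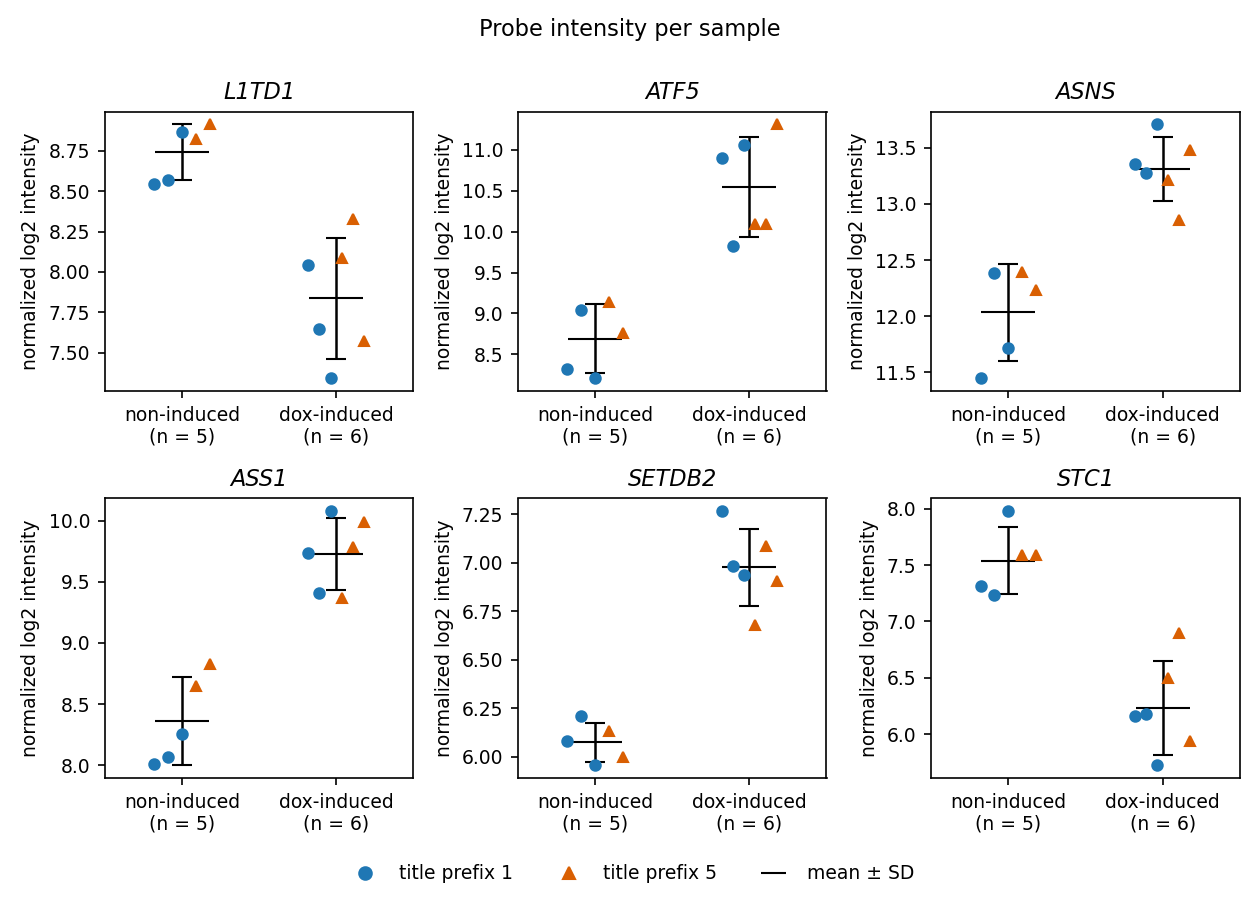
Normalized log2 probe intensity (vertical axis) of L1TD1, ATF5, ASNS, ASS1, SETDB2 and STC1 in each of the 5 non-induced and 6 dox-induced samples, with blue circles for title prefix 1, orange triangles for title prefix 5 and bars for the mean ± SD. L1TD1 was lower in all 6 induced samples than in any of the 5 non-induced samples.

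Which genes differed between induced and non-induced cells was asked over all 11 samples. ATF5, a stress-induced transcription factor, rose 3.62-fold, from a mean log2 level of 8.69 ± 0.42 (SD, n = 5) to 10.55 ± 0.62 (SD, n = 6). ASNS, which makes asparagine, rose 2.43-fold (log2 1.28 ± 0.20, SE), and ASS1, which makes argininosuccinate in arginine synthesis, rose 2.58-fold (log2 1.36 ± 0.18, SE). SETDB2, a member of a histone methyltransferase family, rose 1.87-fold (log2 0.90 ± 0.13, SE), and STC1, a secreted glycoprotein, fell 2.47-fold (log2 -1.31 ± 0.20, SE). The less bright probe of CTH, which makes cysteine, also rose (ILMN_2305116, log2 1.07 ± 0.17, SE, adjusted p = 0.0470), and was named after its values were seen. The brighter CTH probe differed by 0.97 ± 0.19 (SE) with an adjusted p of 0.0838.

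In limma 6 of 14338 probes, 5 higher and 1 lower, in 6 genes, passed an adjusted p of 0.05. The adjusted p was 0.0294 for ATF5, ASS1 and SETDB2 and 0.0296 for ASNS and STC1. At an unadjusted p under 0.05 there were 2329 probes, or 16.2%. The replicate number as a block pairs the samples and leaves dox-induced sample 6 without a partner. In that fit 0 probes passed in limma, against 2004 at an unadjusted p under 0.05. The adjusted p was then 0.229 for ASS1 and 0.240 for ATF5, ASNS, SETDB2 and STC1. As a random block the number gave 21 probes, among them the 6. TRIB3, an inhibitor of stress and insulin signalling, was the nearest of the named genes outside the threshold, 2.95-fold higher (log2 1.56 ± 0.27, SE, adjusted p = 0.0521). Leaving out non-induced sample 1, 3 or 4, or dox-induced sample 1, 3 or 6, left 0 probes in limma, with between 1595 and 2467 at an unadjusted p under 0.05, and leaving out non-induced sample 5 left 1. Leaving out dox-induced sample 2, 4 or 5 gave 26, 16 and 21 probes, and all 11 samples gave 17 with the authors' values or no background correction, 31 with array weights and 1 with no detection filter. Leaving out both non-induced sample 3 and dox-induced sample 5, a choice made after seeing the data, left 1 probe, that of STC1.

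Genes of the ATF4 stress response, through which cells answer amino acid shortage, misfolded protein and blocked mitochondrial translation, were higher together in induced cells. All 29 measured of 33 listed genes had a positive difference, with a mean log2 difference of 0.73 ± 0.13 (SE between samples) and a range from 0.03 for CEBPG to 1.85 for ATF5. Adjusted over the list alone, 23 genes rose, and adjusted over all probes 2 did, ATF5 and ASNS. GDF15, a stress-induced secreted factor, was 1.57 ± 0.38 (SE) higher, and SESN2, a regulator of amino acid signalling, 0.90 ± 0.22 (SE) higher, both among the 23. The transcription factors CEBPB and DDIT3 were 0.95 and 0.99 higher and ATF4 itself 0.41 higher; the mitochondrial enzyme PCK2 was 1.16 and the alanyl-tRNA synthetase AARS1 0.61 higher. These 5 genes were named after their values were seen.

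The ATF4 list was past the threshold in camera with a preset correlation (adjusted p = 3.7e-20) and not with an estimated one (adjusted p = 0.104 with an estimated correlation). The list's mean score was above all 5 non-induced samples in all 6 induced samples (exact two-sided permutation p = 0.00216, the smallest possible, adjusted p = 0.0498). Fry, which tests whether the genes of a list move one way, gave an adjusted p of 0.00459. Fry did not pass with the replicate block (adjusted p = 0.142). Camera with the preset correlation did, at a mean of 0.66 (adjusted p = 4.7e-17; adjusted p = 0.602 with an estimated correlation). In this fit 21 of the 23 genes passed over the list alone. The mean difference was 0.83 ± 0.17 (SE) in prefix 1, with all 29 genes higher, and 0.58 ± 0.19 (SE) in prefix 5, with 27 higher. In prefix 5 camera passed with the preset correlation (adjusted p = 5.3e-14), not with an estimated one (0.254), and fry did not (0.293). List scores there were 0.65 in dox-induced sample 6, 0.14 and 0.11 in dox-induced samples 4 and 5, and -0.21 and -0.34 in non-induced samples. With the replicate block, where sample 6 has no partner, the prefix 5 mean was 0.40 (camera adjusted p = 1.4e-07, fry 0.793).

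**Figure D2:**
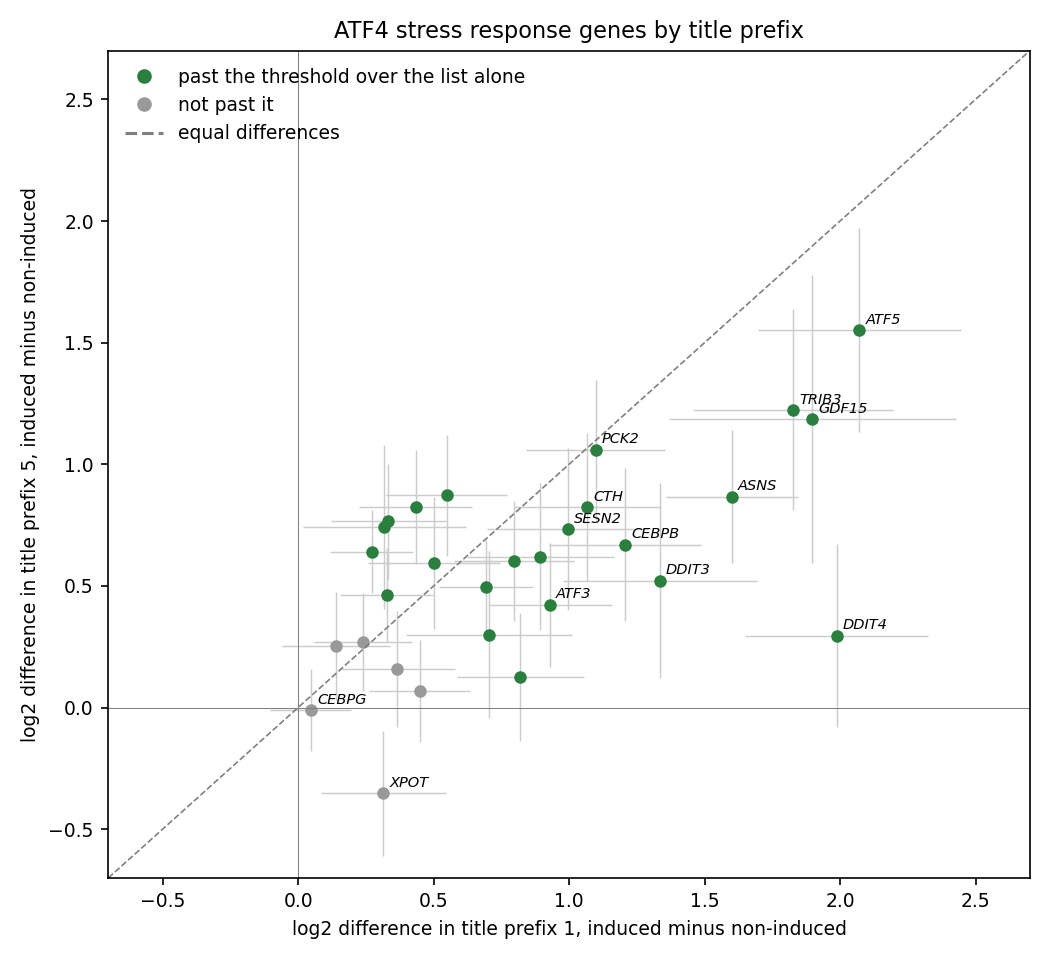
Log2 difference, induced minus non-induced, of each of the 29 measured genes of the ATF4 stress response list in title prefix 1 (horizontal axis) and title prefix 5 (vertical axis), with grey bars of 1 SE, green for the 23 genes past the threshold over the list alone, grey for the others, and a dashed line of equal differences. All 29 genes lie above 0 in prefix 1 and 27 do in prefix 5, and 20 are larger in prefix 1 than in prefix 5, a difference that passed for the list only in camera with the preset correlation and the replicate block.

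Interferon-stimulated and antigen presentation genes were higher in induced cells in 18 of 19 measured members, with a mean log2 difference of 0.41 ± 0.15 (SE). TAP1, a peptide transporter, was 1.31 ± 0.32 (SE) and the class I molecule HLA-B 1.05 ± 0.27 (SE) higher. IFIT1, an antiviral RNA-binding protein, was above background in 0 of 5 non-induced and 5 of 6 induced samples, at least 1.23-fold higher. These 3 genes rose when adjusted over the list alone, and 0 did in limma over all probes, where 5 members had an unadjusted p under 0.05. Only IFIT1 passed over the list with the replicate block, and TAP1 and HLA-B had an adjusted p of 0.0557. MX1, an antiviral GTPase, was 0.56 ± 0.21 (SE) higher without passing either. The list was past the threshold in camera (adjusted p = 5.0e-05), with adjusted p = 0.546 with an estimated correlation and 0.191 in fry. In the exact two-sided permutation the list had an unadjusted p of 0.0390 and an adjusted p of 0.224. Its mean difference was 0.58 ± 0.14 (SE) in prefix 1 and 0.16 ± 0.21 (SE) in prefix 5, where the camera adjusted p was 0.285. The prefix 5 value rests on dox-induced sample 6, with a list score of 0.58 against 0.03 and -0.07 in dox-induced samples 4 and 5. With the replicate block, where sample 6 has no partner, the mean in prefix 5 was -0.04 (camera adjusted p = 0.631).

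Genes of the G1/S step of the cell cycle were lower in induced cells in 24 of 26 measured members, with a mean log2 difference of -0.24 ± 0.08 (SE). RRM2, a subunit of the enzyme that makes deoxynucleotides, fell by 0.54 on the log2 scale (SE 0.14) when adjusted over the list alone, the only member to do so. It did not pass with the replicate block (adjusted p = 0.0957). No member passed in limma over all probes, 0 against 9 at an unadjusted p under 0.05; UHRF1, which maintains DNA methylation, differed by -0.62 ± 0.19 (SE), the polymerase subunit POLA1 by -0.48 and the replication licensing factor CDC6 by -0.43. Camera gave an adjusted p of 3.3e-05, with adjusted p = 0.546 with an estimated correlation and 0.191 in fry. The exact two-sided permutation gave an unadjusted p of 0.0152 and an adjusted p of 0.174. The mean difference was -0.40 ± 0.12 (SE) in prefix 1 and -0.06 ± 0.06 (SE) in prefix 5, where the camera adjusted p was 0.574. Genes of mitosis, the G2/M list, went both ways, 16 of 30 higher and 14 lower, with a mean of -0.03 ± 0.06 (SE) and a median of 0.03; CDC25C, a phosphatase that starts mitosis, was 0.45 higher and the proliferation marker MKI67 -0.45 apart, neither past the threshold (camera adjusted p = 0.714).

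Targets of p53 were higher in 13 of 17 measured members, with a mean log2 difference of 0.29 ± 0.09 (SE). GDF15 and SESN2, also members of the ATF4 list, were the 2 that rose when adjusted over the list alone, and 0 passed in limma over all probes, against 4 at an unadjusted p under 0.05. The death receptor TNFRSF10B was 0.51 ± 0.18 (SE) and the growth arrest gene GADD45A 0.52 ± 0.23 (SE) higher, without passing. GADD45A passed over the list with the replicate block (0.60, adjusted p = 0.0492). Camera gave an adjusted p of 0.0310, with adjusted p = 0.546 with an estimated correlation and 0.191 in fry. The exact two-sided permutation gave an unadjusted p of 0.0260 and an adjusted p of 0.199. Without GDF15 and SESN2, a choice made after seeing the data, the other 15 genes differed by 0.16 ± 0.09 (SE; camera p = 0.0666, exact permutation p = 0.0931). In the model of all samples the camera adjusted p of the whole list was 0.133 in prefix 1 and 0.0249 in prefix 5 (adjusted p = 0.366 with an estimated correlation), where it was 0.178 with the replicate block. The camera call was also lost without dox-induced sample 3, non-induced sample 4 or non-induced sample 5, with adjusted p of 0.113, 0.126 and 0.0876 for the p53 targets, with all probes kept (0.0957) and in the samples of prefix 1 alone (0.0895).

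**Figure D3:**
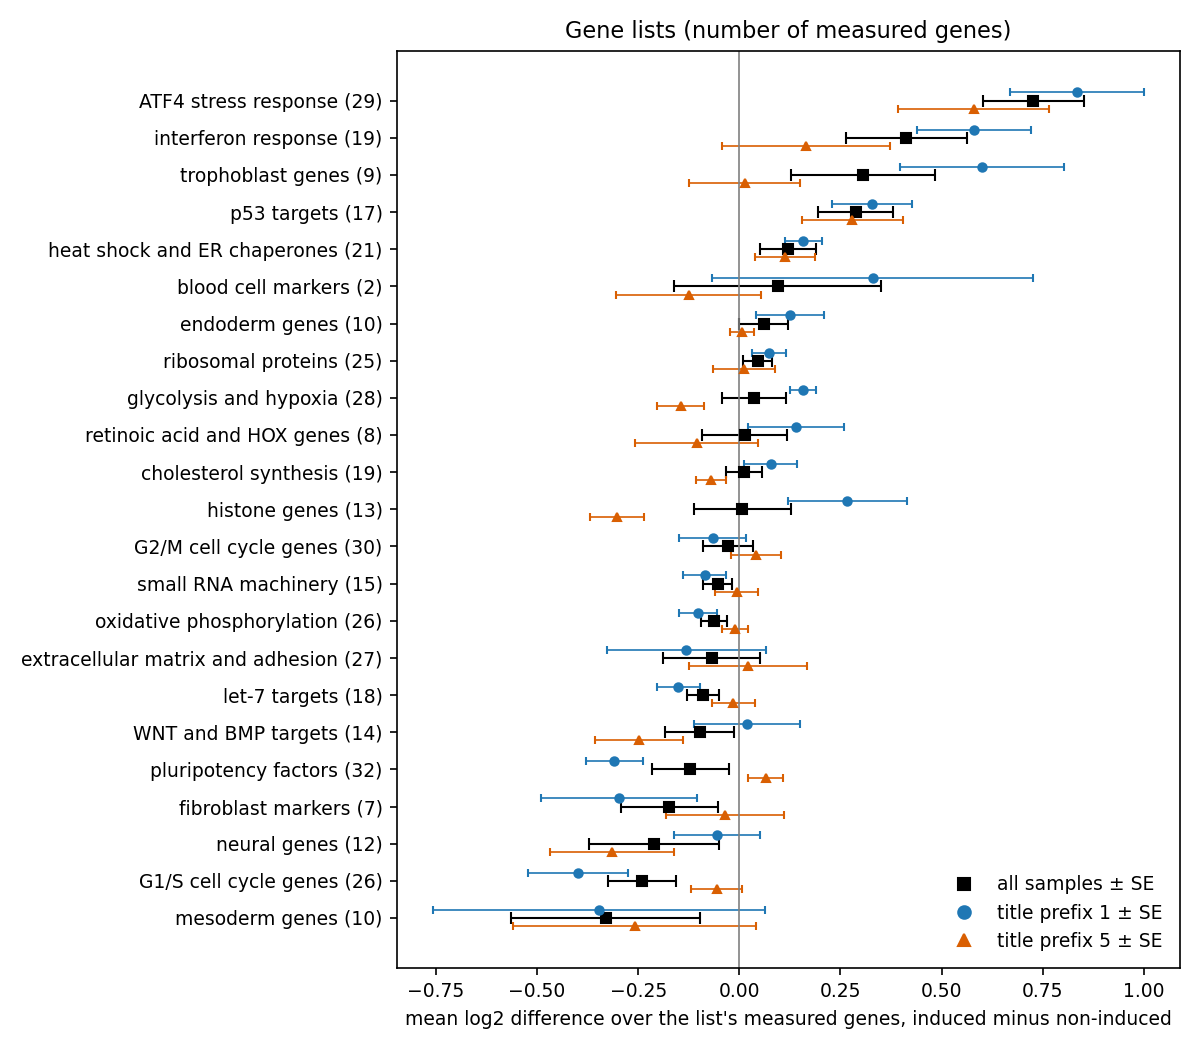
Mean log2 difference, induced minus non-induced, of the measured genes of each of the 23 lists, with black squares for all samples, blue circles for title prefix 1, orange triangles for title prefix 5 and bars of 1 SE between samples. Over all samples the ATF4 stress response has the highest mean, 0.73, and the mesoderm list the lowest, -0.33, which did not pass the test.

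Whether the cells left the undifferentiated state was asked of the pluripotency factors and of early lineage genes. The core factors showed no difference that passed: POU5F1 differed by -0.03 ± 0.23 (SE), SOX2 by -0.45 ± 0.26, NANOG by -0.06 ± 0.20, LIN28A by 0.06 ± 0.12 and DNMT3B, a de novo DNA methyltransferase, by -0.11 ± 0.21, with adjusted limma p of 0.960, 0.408, 0.909, 0.849 and 0.848. The pluripotency list had 20 of 32 measured members lower, with a mean log2 difference of -0.12 ± 0.10 (SE; camera adjusted p = 0.183). The list passed with the replicate block, at -0.17 (camera adjusted p = 0.0101, adjusted p = 0.602 with an estimated correlation). In prefix 1, in the model of all samples, the list passed at -0.31 ± 0.07 (SE; camera adjusted p = 0.00789, adjusted p = 0.405 with an estimated correlation). PRDM14 differed by -0.89 ± 0.28 (SE) and the deubiquitinase USP44 by -0.62 ± 0.17 (SE), JADE1 by 0.45 and SALL2 by -0.26. The less bright JADE1 probes differed by -0.11 and -0.18. In limma 0 members passed over all probes or over the list alone, against 6 at an unadjusted p under 0.05.

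Over all samples no early lineage list passed in camera. Neural genes were lower in 10 of 12 measured members, mean -0.21 ± 0.16 (SE; camera adjusted p = 0.0638), among them NCAM1 by -0.44, GAP43 by -0.57, STMN2 by -0.39 and NES by -0.29. Mesoderm genes were lower in 8 of 10, mean -0.33 ± 0.23 (SE; camera adjusted p = 0.212), with MSX1 at -1.30, COL1A2 at -0.73, TAGLN at -0.42 and PDGFRA at -0.19. Endoderm genes were higher in 7 of 10, mean 0.06 ± 0.06 (SE; camera adjusted p = 0.600), with DAB2 at 0.45, SPARC at 0.39, CXCR4 at -0.59. Trophoblast genes were higher in 8 of 9, mean 0.31 ± 0.18 (SE; camera adjusted p = 0.129). GATA2, a regulator of trophoblast and blood genes, rose by 0.94 ± 0.26 (SE) when adjusted over the list alone (adjusted p = 0.109 with the replicate block) and was above background in 1 of 5 non-induced and 5 of 6 induced samples, while GATA3 was 0.66, TEAD4 0.36 and TFAP2C 0.24 higher. Retinoic acid and HOX genes, which this line raises when it differentiates under retinoic acid, were higher in 5 of 8, mean 0.01 ± 0.11 (SE; camera adjusted p = 0.723), with CYP26B1 at 0.68, HOXD3 at 0.34, CYP26A1 at -0.91 and MEIS2 at -0.43. Tested within a prefix, in the model of all samples, trophoblast genes passed in prefix 1 at 0.60 ± 0.20 (SE; camera adjusted p = 0.0203, adjusted p = 0.483 with an estimated correlation) and neural genes in prefix 5 at -0.31 ± 0.15 (SE; camera adjusted p = 0.0190, adjusted p = 0.254 with an estimated correlation). The neural genes did not pass in prefix 5 with the replicate block, at -0.17 (camera adjusted p = 0.174). Leaving out dox-induced sample 1, 2 or 3 or non-induced sample 3 brought the neural genes past the threshold, at camera adjusted p of 0.0193, 0.0256, 0.0425 and 0.0372. Leaving out dox-induced sample 2 did so for the mesoderm genes (0.0158), and leaving out dox-induced sample 6 for the pluripotency factors (0.0245).

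Signalling and chaperone genes gave single members that passed over their list while the lists over all samples did not. Adjusted over the list alone, ID1, a target of BMP signalling, rose by 0.77 ± 0.23 (SE), and the WNT targets SP5, ZNRF3 and LEF1 fell by 0.58, 0.44 and 0.52; the WNT and BMP list as a whole had a mean of -0.10 ± 0.09 (SE; 8 of 14 lower; camera adjusted p = 0.600). In prefix 5 the WNT and BMP list was at -0.25 ± 0.11 (SE) with a camera adjusted p of 0.0687 in the model of all samples, 0.0421 in the samples of that prefix alone, and adjusted p = 0.366 with an estimated correlation. XBP1, a transcription factor of the unfolded protein response, rose by 0.74 ± 0.15 (SE) over the list of heat shock and ER chaperones (15 of 21 higher, mean 0.12 ± 0.07, SE; camera adjusted p = 0.242), where DNAJB9 was 0.54, HSP90B1 0.32 and PDIA4 0.26 higher. ID1, SP5, ZNRF3, LEF1 and XBP1 did not pass over their lists with the replicate block (adjusted p = 0.0975, 0.0975, 0.0975, 0.105 and 0.0575). In the matrix and adhesion list the epithelial genes CDH1 and EPCAM were 1.58 ± 0.47 (SE) and 0.73 ± 0.26 (SE) higher and SNAI2 was at -0.70, none past the threshold; 14 of 27 members were lower, mean -0.07 ± 0.12 (SE; camera adjusted p = 0.844).

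Over all samples the lists of small RNA biology and of metabolism did not pass. Targets of the let-7 microRNAs were lower in 11 of 18, mean -0.09 ± 0.04 (SE; camera adjusted p = 0.242), with CDK6 at -0.51, CDC25A at -0.38, PLAGL2 at -0.30 and MYCN at -0.27. Small RNA machinery was lower in 8 of 15, mean -0.05 ± 0.04 (SE; camera adjusted p = 0.714), with the helicase DHX9 at -0.50, TNRC6B at -0.35, and DIS3L2 and AGO3 each at 0.30. The less bright DHX9 probes were at 0.22, -0.39 and 0.20. Nuclear genes of oxidative phosphorylation were lower in 16 of 26, mean -0.06 ± 0.03 (SE; camera adjusted p = 0.381), with UQCRB at -0.42, ATP5MC1 at -0.32, NDUFB3 at -0.31 and SDHA at 0.23. Glycolysis and hypoxia genes were higher in 16 of 28, mean 0.04 ± 0.08 (SE; camera adjusted p = 0.911), with P4HA2 at 0.86, VEGFA at 0.71, NDRG1 at 0.47 and SLC2A1 at -0.35; in prefix 5, in the model of all samples, the list passed at -0.15 ± 0.06 (SE; camera adjusted p = 0.0485, adjusted p = 0.289 with an estimated correlation). Cholesterol synthesis genes were higher in 12 of 19, mean 0.01 ± 0.04 (SE; camera adjusted p = 0.911), with LSS at -0.33, HMGCS1 at 0.22, DHCR7 at 0.21 and SCD at 0.16.

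Histone genes and the control lists showed no difference that passed over all samples either. Ribosomal protein genes were higher in 14 of 25, mean 0.05 ± 0.04 (SE; camera adjusted p = 0.714), with RPL37 at 0.44, RPS24 at 0.26, RPL7 at -0.35 and RPS23 at -0.27. Histone genes were higher in 7 of 13, mean 0.01 ± 0.12 (SE; camera adjusted p = 0.714), where camera gave the downward direction against a median of 0.00, with H2BC5 at 0.42, H4C8 at -0.56, H4C3 at -0.27 and H2AZ1 at -0.22. In prefix 5, in the model of all samples, the histone list passed at -0.30 ± 0.07 (SE; camera adjusted p = 0.00828, adjusted p = 0.254 with an estimated correlation), against 0.27 ± 0.15 (SE) in prefix 1, where it did not. Fibroblast markers, which would mark another cell type in the culture, were lower in 6 of 7, mean -0.17 ± 0.12 (SE; camera adjusted p = 0.242), with S100A4 at -0.53, COL6A3 at -0.27, MMP2 at -0.21 and PDGFRB at 0.14. Of the blood cell markers 2 of 16 were measured, CD68 at 0.14 and CD14 at 0.05 (mean 0.09 ± 0.26, SE; camera adjusted p = 0.807).

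The effect of induction was then compared between the title prefixes, since each has both groups. ACTN3, a muscle alpha-actinin, was above background in 0 of 3 non-induced and all 3 induced samples of prefix 1, at least 2.44-fold higher, and differed by -0.63 ± 0.21 (SE) in prefix 5. MB, the muscle oxygen store myoglobin, was above background in 0 of 3 non-induced and all 3 induced samples of prefix 1, at least 2.39-fold higher, and differed by -0.76 ± 0.27 (SE) in prefix 5. The probe ILMN_2106167 of RAP1GDS1, an exchange factor of small GTPases, was at least 1.25-fold lower with induction in prefix 1, where 0 of 3 induced samples were above background, and at least 1.29-fold higher in prefix 5, where 0 of 2 non-induced samples were. The fitted differences between the prefix effects, prefix 5 minus prefix 1, were -2.52 ± 0.28 (SE) for ACTN3, -2.56 ± 0.36 (SE) for MB and 2.20 ± 0.29 (SE) for RAP1GDS1, with adjusted limma p of 0.00913, 0.0382 and 0.0230. Their sizes and errors rest on groups not above background and are not measured folds. The brighter RAP1GDS1 probes ILMN_1806266 and ILMN_1687724 had differences of 0.30 and -0.18 and did not pass. VSNL1 (fitted 1.75, not above background in the induced samples of prefix 1 and the non-induced samples of prefix 5) and CYP26B1 (-1.75) were next and did not pass (0.0939 and 0.102).

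In limma these 3 probes of 14338, 1 higher and 2 lower, were the only ones past the threshold for the difference, against 1770 at an unadjusted p under 0.05. In limma 0 passed with the replicate block, a fit added after seeing the data, against 2674 at an unadjusted p under 0.05. The adjusted p was then 0.0631 for ACTN3, 0.0813 for RAP1GDS1 and 0.0888 for MB. NANOG differed by -0.54 ± 0.19 (SE) in prefix 1 and 0.46 ± 0.21 (SE) in prefix 5; the difference of 1.00 ± 0.28 (SE) has an unadjusted 95% interval from 0.39 to 1.61 and an adjusted p of 0.276. For L1TD1 the difference was 0.11 ± 0.34 (SE), with an interval from -0.62 to 0.84. The count for the difference between prefixes was 0 without non-induced sample 4 or 5, 1 without non-induced sample 1 or 3 or dox-induced sample 1, 4, 5 or 6, 2 without dox-induced sample 2 or 3 and 4 without non-induced sample 2. ACTN3 passed in 9 of these 11 fits, not without non-induced sample 4 or 5 (adjusted p = 0.0844 and 0.0972). RAP1GDS1 passed in 2, without non-induced sample 2 or dox-induced sample 3, and MB in 2, without non-induced or dox-induced sample 2, with adjusted p otherwise from 0.0519 to 0.178 and from 0.0519 to 0.225. The count was also 0 with no background correction and with probes detected on all 11 arrays, with 1 when no probe was filtered.

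Tested for each prefix on its own, in the model of all samples, induction changed 698 probes in prefix 1, 381 higher and 317 lower, in 546 genes, and 0 in prefix 5. At an unadjusted p under 0.05 there were 3437 and 845 probes, or 24.0% and 5.89%, the latter near the share that no effect would give. With limma on the samples of each prefix alone 507 and 0 probes passed. The replicate block gave 1356 in prefix 1, 724 higher and 632 lower, with 687 of the 698 among them. It gave 0 in prefix 5 in limma, against 930 at an unadjusted p under 0.05. Among the genes that rose in prefix 1 were CYP26B1, which degrades retinoic acid, by 1.47 ± 0.19 (SE, adjusted p = 0.0103), TAP1 by 1.80 ± 0.35 (SE, adjusted p = 0.0195), CDH1 by 2.27 ± 0.55 (SE, adjusted p = 0.0393) and GATA3 by 1.34 ± 0.29 (SE, adjusted p = 0.0293). PRDM14 differed by -1.48 ± 0.31 (SE, adjusted p = 0.0267) and USP44 by -0.92 ± 0.20 (SE, adjusted p = 0.0283), both past the threshold in prefix 1. In prefix 5 these 6 genes differed by -0.27, 0.57, 0.58, -0.11, -0.22 and -0.21, and the difference between prefixes passed for none of them. The prefix 5 values of TAP1, CDH1, PRDM14 and USP44 rest largely on dox-induced sample 6, while the negative values of CYP26B1 and GATA3 do not. CDH1 was at a log2 level of 11.144 in that sample, against 8.714 and 8.996 in dox-induced samples 4 and 5. In non-induced samples 4 and 5 CDH1 was at 9.314 and 8.754. PRDM14 was at 6.89 in dox-induced sample 6, against 7.72 and 8.29 in dox-induced samples 4 and 5. Of the 698 probes, 471 (67.5%) had the same direction in prefix 5, against 53.1% of all probes. Their median absolute difference in prefix 5 was 0.196 of that in prefix 1, where they were selected. Probes are not independent replicates, and no splits were taken for this share. Leaving out non-induced sample 1 or 3 or dox-induced sample 1 or 3 reduced the 698 to 1, 41, 3 and 2; without non-induced sample 4 or 5 it was 314 each time; without dox-induced sample 2 or 6 it was 1052 and 1138; and without dox-induced sample 5 the count in prefix 5 was 1.

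Gene lists were compared between the prefixes in the same way. Pluripotency factors had a mean log2 difference of -0.31 ± 0.07 (SE) in prefix 1 and 0.06 ± 0.04 (SE) in prefix 5, a difference of 0.37 (camera adjusted p = 0.00780). G1/S genes differed between prefixes by 0.34, interferon genes by -0.42, trophoblast genes by -0.59, glycolysis and hypoxia genes by -0.30 and histone genes by -0.57 (camera adjusted p = 0.00122, 0.0180, 0.0391, 0.0391 and 0.0188). For these 6 lists the adjusted p with an estimated correlation was 0.351, 0.424, 0.727, 0.424, 0.379 and 0.351, in the order given, so 0 lists passed; 0 passed in fry and 0 after adjustment in an exact permutation within prefixes. That exact p was 0.015 for the pluripotency factors, 0.01 for glycolysis and hypoxia and 0.015 for histone genes, each 0.115 after adjustment. Histone genes did not pass in camera with the replicate block (adjusted p = 0.0588). The ATF4 list did, at -0.43 (camera adjusted p = 0.0143, adjusted p = 0.727 with an estimated correlation). Glycolysis and hypoxia genes passed in fry in that fit (adjusted p = 0.00428).

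Levels also differed between the prefixes with the induction taken into account. DNAJA4, a co-chaperone, was 2.16 ± 0.24 (SE) higher in prefix 5 (adjusted p = 0.00218). NLRP7, a gene of oocytes and early embryos, was higher in prefix 5 by 1.74 ± 0.22 (SE) with probe ILMN_1652366 and at least 1.26-fold with probe ILMN_1798063 (adjusted p = 0.00551 for both). The latter probe was above background in 0 of 6 samples of prefix 1 and in all 5 of prefix 5. DNAJA4 and the probe ILMN_1652366 were above background in 0 of 3 non-induced and 2 of 3 induced samples of prefix 1. Their sizes therefore rest largely on values near background in that prefix. The developmental transcription factors TFAP2A and DLX5 were lower in prefix 5, with log2 differences of -2.12 ± 0.30 and -2.03 ± 0.31 (SE, adjusted p = 0.0176 and 0.0355). DLX5 was above background in 1 of 2 non-induced and 0 of 3 induced samples of prefix 5. The size for DLX5 therefore rests largely on values near background in prefix 5. In limma 11 probes passed, 6 higher and 5 lower in prefix 5, in 8 genes, against 1631 at an unadjusted p under 0.05. This fit took same-numbered samples, which share a prefix, as independent. The count was 0 with probes detected on all 11 arrays, 4 without non-induced sample 1 or dox-induced sample 4, 5 without dox-induced sample 1 or 2, 6 without non-induced sample 2 or 4 or dox-induced sample 3, 7 without dox-induced sample 6 and 20 without non-induced sample 3. DNAJA4 and both NLRP7 probes passed with any single sample left out. TFAP2A did not without non-induced sample 1 or dox-induced sample 1 or 4 (adjusted p = 0.0706, 0.0502 and 0.0626), and DLX5 passed only without non-induced sample 3 or 5, with adjusted p otherwise from 0.0566 to 0.172.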

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

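All tests weighed in this part for the ATF4 genes except that of knockdown depth, and the interval of the L1TD1 effects between prefixes, were chosen after the result was seen, as were the correlation of the prefix effects across probes, the exact permutations within prefixes, the comparisons of gene lists between prefixes, the replicate block within and between prefixes and the splits that part all pairs.

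The ATF4 stress response genes were higher in induced cells by a mean log2 difference of 0.73. The choice of background correction is argued against as the source, since over 4 other settings the lowest mean was 0.67 (0.667, SE 0.115). All 4 bring the arrays to common quantiles or a common median, so they cannot test normalization between arrays itself. A single sample is argued against too, since the lowest mean with a sample left out was 0.66 (0.663, SE 0.119). Chance is argued against among the samples in the series over 100 splits that do not use the pairs. The real split, at 0.727, was the highest and 0.674 the highest other, with 1 of 100 as large. Since the list was singled out as the largest of 23, the largest mean of any list was also taken in all 462 splits, and 1, the real one, was as large, with 0.720 as the highest other. The sample left out by the submitters because it did not group with its condition favours the real split, and what it would have changed cannot be tested. Doxycycline itself may raise such genes by blocking mitochondrial translation and cannot be told apart from the loss of L1TD1, because 0 induced samples lacked the hairpin. Depth of knockdown stays open as well: over the 6 induced samples L1TD1 and the list score had r = -0.77 (-0.765, exact permutation p = 0.0778) and rho = -0.886 (exact p = 0.0333), and r = -0.55 without the 2 samples farthest from the median of L1TD1, where no p was computed.

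Induction changed 507 probes in the 6 samples of prefix 1 alone, or 698 in the model of all samples and 1356 with the replicate block, and 0 in the 5 samples of prefix 5, where limma gave 853 and 845 probes (5.95% and 5.89%) at an unadjusted p under 0.05. Fewer non-induced samples in prefix 5 may account for it and cannot be told apart from a weaker effect, since the 698 became 1 and 41 without non-induced sample 1 or 3 of prefix 1 but 837 without non-induced sample 2, so that 3 induced against 2 non-induced samples can also give many calls. A shallower knockdown in prefix 5 stays open too, since the unadjusted 95% interval of the difference in the L1TD1 effect runs from -0.62 (-0.618) to 0.84 (0.843). The effects in both prefixes correlated across probes at r = 0.129, where probes are not independent replicates, and 4 of 10 splits of the prefix 5 samples gave as high a value, the highest other being 0.366. The 10 splits of the prefix 1 samples are too few for a share under 0.05; the real split gave 507 probes and the highest other 0, so 1 of 10 was as large, and a biological difference between the shRNAs or clones of the prefixes was not tested apart from these.

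Over the splits of all samples, the count of 6 probes changed by induction was reached by 1 of 100, the real one, with 2 as the highest other. Chance is therefore argued against for that count among the samples in the series, in the fit without the pairs and with the same reserve about the sample left out. That count was 0 with the replicate block. Of the 32 splits that part all 5 pairs of same-numbered samples, the real one and 31 that swap 1 to 5 pairs, 1 gave as many probes (highest other 1), 1 as large a mean of the ATF4 list (highest other 0.596) and 15 as many lists (highest other 11). With 32 splits no share can be under 0.031, and the largest mean of any list was not taken over them. With the replicate block all 32 splits gave 0 probes, so they cannot test the count in that fit. The count of 4 gene lists past the threshold was reached by 37 of 100 splits, with 9 as the highest other, so chance cannot be excluded for it. The count of 11 probes that differ between title prefixes was reached by 1 of 100, with 0 as the highest other. These splits part same-numbered samples, which share a prefix. They therefore cannot tell a difference between prefixes from differences between clones.

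The effect of induction differed between prefixes, prefix 5 minus prefix 1, for ACTN3 (-2.52), MB (-2.56) and RAP1GDS1 (2.20) in limma, fitted values that rest on groups not above background; 0 passed with the replicate block (2674 at an unadjusted p under 0.05). With camera at the preset correlation it differed for the pluripotency factors (0.37), trophoblast genes (-0.59), G1/S genes (0.34), interferon response (-0.42), glycolysis and hypoxia (-0.30) and histone genes (-0.57), and for 0 lists with an estimated correlation, in fry or in the exact permutation after adjustment. With the replicate block the histone genes did not pass in camera, and the ATF4 list did (-0.43), though not with an estimated correlation (camera adjusted p = 0.727).

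Single samples far from the rest of their group were found in 11 of 260 groups of values tested, where chance gives about 13. Among dox-induced samples, JADE1 in sample 6 was at a log2 level of 11.64 (others 10.6 to 10.97), RPS24 in sample 6 at 12.57 (12.13 to 12.28) and STMN2 in sample 5 at 5.26 (5.89 to 6.23). Among non-induced samples, GAP43 in sample 3 was at 9.11 (7.69 to 7.98), MEIS2 in sample 3 at 8.72 (8.19 to 8.32), CDC6 in sample 2 at 6.96 (6.4 to 6.55), ATP5MC1 in sample 4 at 11.49 (11.17 to 11.25) and EPCAM in sample 4 at 12.28 (11.65 to 11.82). Mean list scores of non-induced samples stood apart for the endoderm genes in sample 3, at 0.10 (others -0.09 to -0.05), the matrix and adhesion genes in sample 3, at 0.32 (-0.06 to -0.02), and the cholesterol genes in sample 1, at -0.14 (0.02 to 0.05).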

How the results depend on the processing

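The exact permutations, the lists between prefixes, the replicate block within and between prefixes and the fit without non-induced sample 3 and dox-induced sample 5 were chosen after the result was seen; the cause of a change was not tested except where fewer samples or other probes were used. The number of probes changed by induction, 6, was 0 in limma with the replicate block (2004 at an unadjusted p under 0.05, smallest adjusted p = 0.229), 21 with the replicate number as a random block (14 higher, 7 lower), 4 with the title prefix as a block, 507 in prefix 1 alone and 0 in prefix 5 alone (853 unadjusted). It was 17 (12 higher, 5 lower) with no background correction, with normexp at an offset of 50, with the authors' values and with a variance trend, 1 with no detection filter, 13 with probes detected on all 11 arrays, 31 (18 higher, 13 lower) with array weights, 1 without non-induced sample 3 and dox-induced sample 5, and 0 to 26 with a sample left out. The 6 probes were all among those called under each setting that gave at least 13. Beyond the calls given with the results, the replicate block ended those of NUPR1 and SARS1 over the ATF4 list (adjusted p = 0.0559 and 0.0535). Over all samples it changed no other call of a named gene or list. Within prefix 1 it ended the fry calls of the ATF4 list (adjusted p = 0.0399 without and 0.0709 with the block) and of the G1/S genes (0.0399 and 0.0835). It brought glycolysis and hypoxia genes past the threshold in fry there (0.0980 and 0.0404). Changed calls of single named genes within prefix 1 are not listed. L1TD1, at -0.91, kept its direction everywhere and passed in prefix 1 alone (-0.98), with no background correction (-0.75), normexp (-0.77), the authors' values (-0.75) and array weights (-0.90), with a range of -1.004 to -0.81 with a sample left out and adjusted p from 0.0351 to 0.835 over all alternatives. Lists past the threshold, 4, were 0 with an estimated correlation, 1 in fry, 1 in the exact permutation and 3 to 6 with a sample left out. The lists that differ between prefixes, 6, were 0 with an estimated correlation, in fry and in the exact permutation. The probes that differ in the effect between prefixes, 3, were 0 with the replicate block, no background correction, normexp, the authors' values and detection on all 11 arrays, 1 with no filter and 0 to 4 with a sample left out. The probes that differ in level, 11, were 0 with detection on all 11 arrays and 4 to 20 with a sample left out. Of named genes and lists outside leave-one-out, 1266 and 335 values kept direction and side of the threshold, 29 and 5 newly passed, 20 and 12 no longer passed, and 15 and 16 turned direction. In prefix 1 alone these were LIN28A (-0.044) and the WNT and BMP targets (0.019). In prefix 5 alone they were POU5F1 (0.065), NANOG (0.46), DNMT3B (0.40), GAP43 (0.075), PDGFRA (0.10), COL1A2 (0.22), GATA3 (-0.11), CYP26B1 (-0.27), VEGFA (-0.11), H2BC5 (-0.51), RPL37 (-0.064) and CD14 (-0.25), and the lists of pluripotency factors (0.065), retinoic acid and HOX (-0.11), G2/M (0.041), glycolysis and hypoxia (-0.15, past the threshold at adjusted p = 0.0421), cholesterol (-0.070), matrix and adhesion (0.021), histones (-0.30, past the threshold at adjusted p = 0.000949) and blood markers (-0.13). Median scaling turned cholesterol (-0.0049), no filter turned endoderm (-0.0022) and blood markers (-0.054), detection on all 11 arrays turned matrix and adhesion (0.021) and WNT and BMP (0.056), and array weights turned histones (-0.010). Without non-induced sample 3 and dox-induced sample 5, POU5F1 (0.069), DNMT3B (0.064) and histones (-0.036) turned. With a sample left out, values crossed 0 for POU5F1 (-0.21 to 0.11), NANOG (-0.21 to 0.042), DNMT3B (-0.22 to 0.021), CD68 (-0.035 to 0.34), CD14 (-0.11 to 0.22), retinoic acid and HOX (-0.053 to 0.085), cholesterol (-0.023 to 0.028), matrix and adhesion (-0.13 to 0.0038), histones (-0.067 to 0.058) and blood markers (-0.073 to 0.25).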

Other observations

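The tests of transfer RNA synthetases and of mitochondrial proteins were chosen after the ATF4 result was seen, on lists written before they were tested, and the genes named here were chosen after their values were seen. Cytosolic transfer RNA synthetases outside the ATF4 list, which load amino acids for protein synthesis, were higher in induced cells in 12 of 14 measured members, with a mean log2 difference of 0.21 ± 0.05 (SE; exact permutation p = 0.00216, the smallest possible, adjusted p = 0.00866 over 4 lists). Their mean was 0.16 in prefix 1 and 0.28 in prefix 5. GARS1, EPRS1 and YARS1, by 0.53, 0.53 and 0.51, rose when adjusted over the list alone, and 0 members passed in limma over all probes, against 6 at an unadjusted p under 0.05. Mitochondrial synthetases went both ways, 7 of 13 higher, with a mean of 0.01 ± 0.04 (SE; exact permutation p = 0.872), -0.10 in prefix 1 and 0.12 in prefix 5.

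Genes of mitochondrial ribosomal proteins were lower in 52 of 69 measured members, with a mean log2 difference of -0.14 ± 0.04 (SE; exact permutation p = 0.00433, adjusted p = 0.00866). No member passed in limma, 0 against 17 at an unadjusted p under 0.05; MRPL15 differed by -0.54 and MRPL33 by -0.53. The mean was -0.23 in prefix 1 and -0.04 in prefix 5. Mitochondrial chaperones and proteases were higher in 8 of 13 members, with a mean of 0.12 ± 0.05 (SE; exact permutation p = 0.0238, adjusted p = 0.0317), 0.035 in prefix 1 and 0.22 in prefix 5; the protease LONP1, by 0.51, rose when adjusted over the list alone, the chaperone TRAP1 was 0.34 higher, and HSPD1 and HSPE1 differed by -0.10 and -0.19.

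A candidate explanation for the synthetases is an ATF4-type response rather than a general change of translation genes. The cytosolic list lay above the mitochondrial list by 0.20 (0.201, SE 0.0564; exact permutation p = 0.00866), as this needs, though the ATF4 factor itself was not measured as protein. This comparison holds synthetases only and does not measure translation genes at large. The added lists were not tested with the replicate block. A mitochondrial unfolded protein response may go with the chaperones and proteases, whose mean of 0.12 (0.118) passed the exact test (p = 0.0238), while HSPD1 and HSPE1 had negative differences. Both lists had their larger mean in prefix 5, where that of the ATF4 list was the smaller, 0.58 against 0.83; these differences between prefixes were not tested for the added lists. Neither test separates the hairpin from doxycycline.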
